A study of Mus musculus with 16 samples.

How the data were processed

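The deposited file holds raw counts of reads assigned by the authors to mature mouse miRNAs, with 1978 named miRNAs and 16 libraries. Each name occurs once. Per the labels, RNA came from perinatal mouse forebrain neurons kept in primary culture and transduced with lentivirus, and 100 ng of total RNA went into a small RNA kit with 15 PCR cycles and gel size selection. Trim Galore 0.6.0, cutadapt 1.15, Bowtie 1.1.1 and edgeR are named by the authors without saying which step each served, and their genome build is GRCm38.p6. Raw reads were not used here. The labels name no batch, culture or animal, and they do not say that the 4 replicates of a group came from separate cultures or separate animals. Reads amplified by PCR were counted without molecular identifiers, so the detection floors printed here cover counting error only. The standard errors and intervals of fold changes rest on the fitted spread between libraries.

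All 16 libraries were fitted together, with 1 coefficient per group and 12 residual degrees of freedom. Libraries were scaled by the trimmed mean of M values, low counts were removed by edgeR's own filter, and a robust quasi-likelihood F test was run in edgeR 4.0.16 with limma 3.58.1 under R 4.3.3. P values were adjusted by Benjamini and Hochberg over the 483 tested miRNAs of each comparison, and a miRNA is said to have risen, fallen or changed when the adjusted p was below 0.05. The filter left out 1495 miRNAs, of which 611 had no count in any library. Fold changes are log2 values from that model, and their ± standard error was derived from the fold change and its F statistic. Levels are counts per 1 M of the library total scaled as above (CPM), with the standard deviation over 4 libraries. They therefore differ from shares of a library. CPM thresholds and detection floors used the unscaled totals. Intervals have nominal 95% coverage, and those of fold changes used a t distribution with 12 degrees of freedom. These choices, the lists of miRNAs, the comparisons and the rule for naming miRNAs were written down before the data were examined.

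A miRNA is named as an example when its adjusted p was below 0.05, its mean was at least 10 CPM and every hairpin library lay on the same side of every empty-vector library, taking the 10 largest rises and 10 largest falls of a comparison (5 and 5 between hairpins). The 10 most abundant miRNAs and up to 4 changed members of each list, or its 2 most abundant members, were named too. With 4 libraries against 4, complete separation is met by chance in 2.86% of miRNAs, and with 12 against 4 in 0.11%.

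Lists of miRNAs were fixed in advance by name: the Dlk1-Dio3 imprinted cluster, neuron-enriched miRNAs, miR-17-92 and its paralog clusters, let-7 with miR-98, the miR-29, miR-30, miR-181 and miR-34/449 families, miRNAs made without the Microprocessor, and markers of astroglia, oligodendrocytes, microglia, vessels and fibroblasts, erythroid cells and inflammation. Lists with at least 5 tested members were tested with camera in limma, with a preset correlation of 0.01 and a prior count of 2, adjusted over 40 tests (10 lists by 4 comparisons with the empty vector). Camera was repeated with the correlation estimated from the libraries, and member p values were also adjusted over the list alone. Of the 40 tests, 19 passed with the preset correlation and 3 with an estimated correlation, while the rotation test fry gave 35 and its mixed form 37. Genomic positions came from RefSeq on GRCm38.p6, the build of the authors, and host genes and precursor sequences from GENCODE M21 on GRCm38. Of the tested miRNAs, 479 were matched to a precursor gene and 475 to a precursor sequence. The labels hold no mature sequences, so the GC content used in the closing section is that of the side of the precursor holding the arm, and a match to another RNA is a shared stretch of 20 bases.

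Some names cannot be separated, because 14 tested miRNAs had counts identical to another name in every library, among them miR-199a-3p with miR-199b-3p and miR-486a-3p with miR-486b-3p. They count as separate tests in the totals. The 4 tested erythroid miRNAs are all such names, the arms of miR-486a and miR-486b, with identical counts for the same arm. MiR-451a and miR-144 of that list were not tested.

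Shared replicate numbers were checked as a possible pairing, by correlating libraries of the same number after removing group means over 360 miRNAs of at least 10 CPM. The 4 correlations of shRNA with the empty vector were 0.11 to 0.281, and those of shRNA_2bp with shRNA were 0.149 to 0.192, above the threshold of 0.1, with 8 of 8 libraries correlating best with their own number. For shRNA_2bp against the empty vector the lowest was 0.085 (3 of 8), but it was 0.165 over 229 miRNAs above 50 CPM, so the answer there depends on a threshold set after the second set of values was seen and before any blocked fit was run. None of the 3 comparisons with shRNA_5bp passed. A fit blocked on replicate number was therefore run as an alternative for every comparison.

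The scripts were tested on simulated data in 11 draws per comparison, each simulated from the empty-vector means, the fitted dispersions and the real library totals with 200 miRNAs moved by a known amount. The share of false calls averaged 2.5% for shRNA (0.6 to 5.3%), 3.1% for shRNA_2bp (1.3 to 8.2%) and 3.1% for shRNA_5bp (1.9 to 5.9%) at the depths of those groups. Changes of 1 on the log2 scale were recovered in 96.7, 88.5 and 88.3% of cases, and changes of 0.5 in 70, 62.5 and 58.4%. A planted list was found by camera in limma (adjusted p = 5.59e-70) with 0 other lists passing. The simulated miRNAs were drawn independently, so false list calls from correlated members were not tested. An arm shift of 0.5 planted in shRNA was read as 0.53 (exact p = 0.0286 before adjustment over the hairpins). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.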

Results

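MiRNAs were counted in cultured mouse forebrain neurons that had received an empty lentiviral vector, an shRNA, or that shRNA carrying 2 or 5 point mutations (shRNA_2bp and shRNA_5bp), with 4 libraries per group. The neuronal miR-128-3p was the most abundant miRNA and held 38.7 ± 0.8% of all counts with the empty vector. Its share was 33.1 ± 1.2% with shRNA, 24.7 ± 0.6% with shRNA_2bp and 26 ± 2% with shRNA_5bp (mean ± SD). Every library of each hairpin group lay below every empty-vector library (exact p = 0.0286, adjusted p = 0.0343 for each). Library totals differed as well, at 7.42 ± 4.24 M counts with the empty vector, 6.3 ± 1.22 M with shRNA, 1.58 ± 0.393 M with shRNA_2bp and 1.43 ± 0.759 M with shRNA_5bp. The last 2 groups lay below the empty vector without overlap (exact p = 0.0286, adjusted p = 0.0343), so depth differed along with the group, while shRNA overlapped it (exact p = 0.6857). In all, 483 miRNAs were tested, and they held at least 99.941% of the counts of every library. On the first 2 principal components, with 46% and 27.6% of the variance, the empty vector and shRNA lay together at -8.21 to -11.86 on the first axis. ShRNA_2bp (5.05 to 7.42) and shRNA_5bp (9.51 to 14.78) lay apart on the first axis and on opposite sides of the second.

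**Figure D1:**
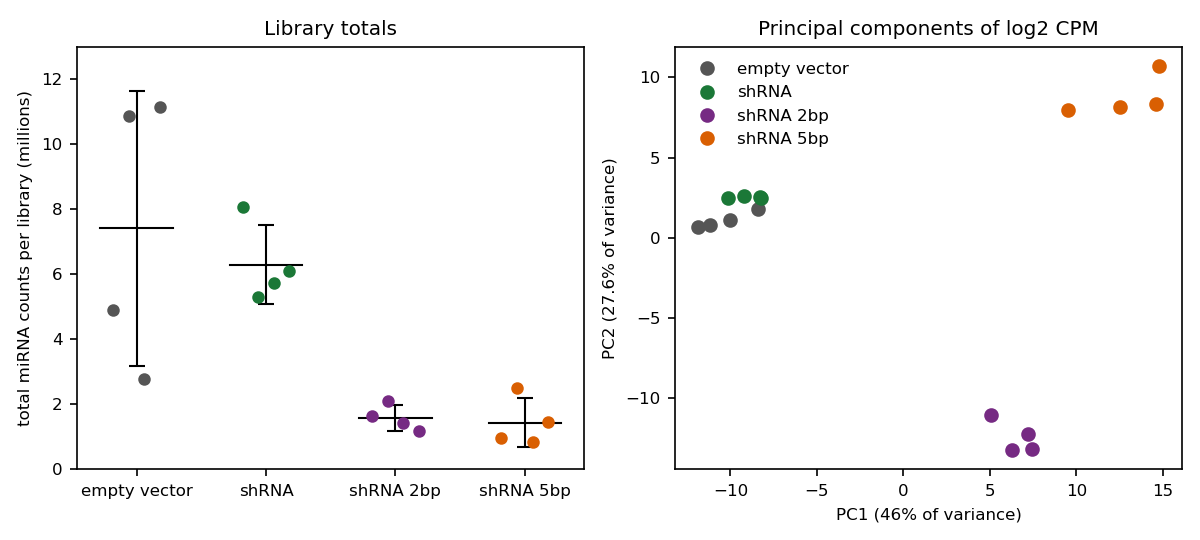
Left, total counts of each library in M by group, with shRNA_2bp and shRNA_5bp (1.58 and 1.43 M on average) below the empty vector (7.42 M). Right, first and second principal components of the 16 libraries (46% and 27.6% of the variance), each dot 1 library coloured by group.

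With shRNA, miR-7b-5p and miR-7a-5p of the neuronal miR-7 family rose most clearly. MiR-7b-5p rose by 2.02 ± 0.063 on the log2 scale (± SE, 4 libraries per group), from 1378 ± 89.2 to 5601 ± 187.6 CPM (adjusted p = 6.15e-21). MiR-7a-5p rose by 1.54 ± 0.062, from 6738 ± 658.1 to 19620 ± 959 CPM (adjusted p = 3.03e-18). The activity-regulated miR-132-3p (0.95 ± 0.067, adjusted p = 3.59e-12) and miR-212-3p (0.92 ± 0.122, adjusted p = 6.51e-07), processed from 1 primary transcript, rose. So did miR-129-2-3p (1.20 ± 0.109, adjusted p = 3.68e-09) and miR-672-5p (0.92 ± 0.098). The inflammation-linked miR-155-5p rose by 2.19 ± 0.263, from 3.51 ± 1.074 to 14.97 ± 2.651 CPM (adjusted p = 1.35e-07). Muscle-type miR-1a-3p fell by 2.02 on the log2 scale (SE 0.16, from 44.1 to 10.79 CPM, adjusted p = 3.82e-11), hypoxia-induced miR-210-3p fell by 1.47 (SE 0.246), and miR-375-3p fell by 1.04 (SE 0.152). MiR-370-3p fell from 18770 ± 1036 to 11540 ± 340.1 CPM (-0.70 ± 0.052, adjusted p = 1.04e-11) and miR-128-3p from 427200 ± 14820 to 331300 ± 22710 CPM (-0.37 ± 0.065, adjusted p = 4.84e-05). In total 168 of 483 miRNAs changed, 95 up and 73 down, of which 13 rose and 6 fell more than 2-fold, and 143 of the 168 separated the groups completely. Among all tested miRNAs 159 (32.9%) did so, against 2.86% by chance. Scaling by library size alone moved the median of all miRNAs from 0.04 to 0.18 and the share of rises from 56.5% to 77.2%. The share was also 66.9% without empty-vector library 3, 66.7% without shRNA library 1 and 69.6% without shRNA library 2.

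Of 80 tested miRNAs from the imprinted Dlk1-Dio3 region, which holds the largest miRNA cluster of the mouse brain, 36 fell and 5 rose with shRNA (median -0.29, camera adjusted p = 7.73e-11, and adjusted p = 0.0304 with an estimated correlation). When adjusted over the list alone 37 fell and 5 rose. Members moved in both directions. MiR-341-5p fell by 1.59 (SE 0.281), miR-323-5p by 0.67 (SE 0.131) and miR-433-3p by 0.36 (SE 0.06). MiR-431-5p rose by 1.37 ± 0.093 (from 120.4 to 311.4 CPM, adjusted p = 2e-12) and miR-668-3p by 0.80 ± 0.098. All 5 tested members of the miR-34/449 family, which did not include miR-449a, rose (median 0.84, camera adjusted p = 0.0109, and adjusted p = 0.21 with an estimated correlation). Among them were miR-34c-3p (1.53 ± 0.276) and miR-34b-5p (1.01 ± 0.26). Of 30 neuron-enriched miRNAs 11 rose and 5 fell (median 0.12, camera adjusted p = 0.0628). Without empty-vector library 2 or 3, or shRNA library 1 or 2, 3 fell. The camera adjusted p was 0.0432 without empty-vector library 2 and 0.0393 without 3. It was 0.0465 without shRNA library 2, 0.0407 without 4 and 0.0484 without shRNA_2bp library 2. In the miR-30 family 4 of 11 rose and 1 fell (5 and 2 when adjusted over the list alone), including miR-30a-5p at 0.38 ± 0.058. None fell without empty-vector library 1, 2 or 3, any shRNA library, shRNA_2bp library 1 or 2, or shRNA_5bp library 4. There were 2 falls without empty-vector library 4, shRNA_2bp library 3 or 4, or shRNA_5bp library 1 or 2, and 2 with the replicate block. In the miR-181 family 3 of 8 rose and 1 fell, its list median (-0.02) being opposite in sign to its mean (0.07) and to the upward direction of the test (adjusted p = 0.618). That median was 0.01 to 0.09 without empty-vector library 1, 2 or 3, any shRNA library or shRNA_5bp library 4. MiR-181a-5p rose by 0.75 ± 0.065 and miR-181c-5p by 0.84 ± 0.14. Among 19 let-7 and miR-98 members 0 rose and 1 fell (0 when adjusted over the list alone), but 9 rose and 0 fell with library-size scaling, and 4 rose and 3 fell with the replicate block. Between 1 and 5 rose, with 0 or 1 falls, without empty-vector library 2 or 3, any shRNA library, shRNA_2bp library 1 or 2, or shRNA_5bp library 1, 3 or 4. None rose and 3 fell without empty-vector library 4, shRNA_2bp library 3 or 4, or shRNA_5bp library 2 (median -0.06 to -0.02), and 0 fell without empty-vector library 1. The list median was 0.02 and its mean 0.03, with a downward test (adjusted p = 0.93). Of 11 miR-17-92 members 1 rose (3 without empty-vector library 3, and 2 without empty-vector library 1, shRNA library 3 or shRNA_5bp library 4). Of 4 miR-29 members 2 rose, including miR-29a-3p (0.59 ± 0.087), but 1 without empty-vector library 2, 3 or 4, shRNA library 4 or shRNA_2bp library 4.

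Among markers of other cell types, of 7 astroglia-leaning miRNAs 3 rose (median 0.05, and -0.01 without shRNA_2bp library 4; camera adjusted p = 0.257), including miR-21a-5p at 0.30 ± 0.069. No vascular and fibroblast miRNA of 8 (adjusted p = 0.559), oligodendrocyte miRNA of 3 or erythroid miRNA of 4 changed. However, 1 oligodendrocyte miRNA rose without empty-vector library 3, shRNA library 1, or shRNA_5bp library 3 or 4. Without empty-vector library 4, 2 erythroid names with identical counts fell. Of the vascular miRNAs 1 fell without empty-vector library 1, shRNA_2bp library 3 or 4, or shRNA_5bp library 2, and 2 rose without shRNA_5bp library 3. Both tested microglia and leukocyte miRNAs, miR-155-5p and miR-146a-5p, rose, and they are also 2 of the 4 inflammation miRNAs. The counts held 11 names of the microglia list, of which only these 2 passed the filter. No microglia marker outside the inflammation list was therefore tested. In that inflammation list 3 of 4 rose, with miR-146a-5p at 0.48 ± 0.122. Of 9 miRNAs made without the Microprocessor 4 rose (1 without empty-vector library 4), including miR-1839-5p, whose precursor shares 20 bases with another non-coding RNA, at 0.33 ± 0.067 (camera adjusted p = 0.229).

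**Figure D2:**
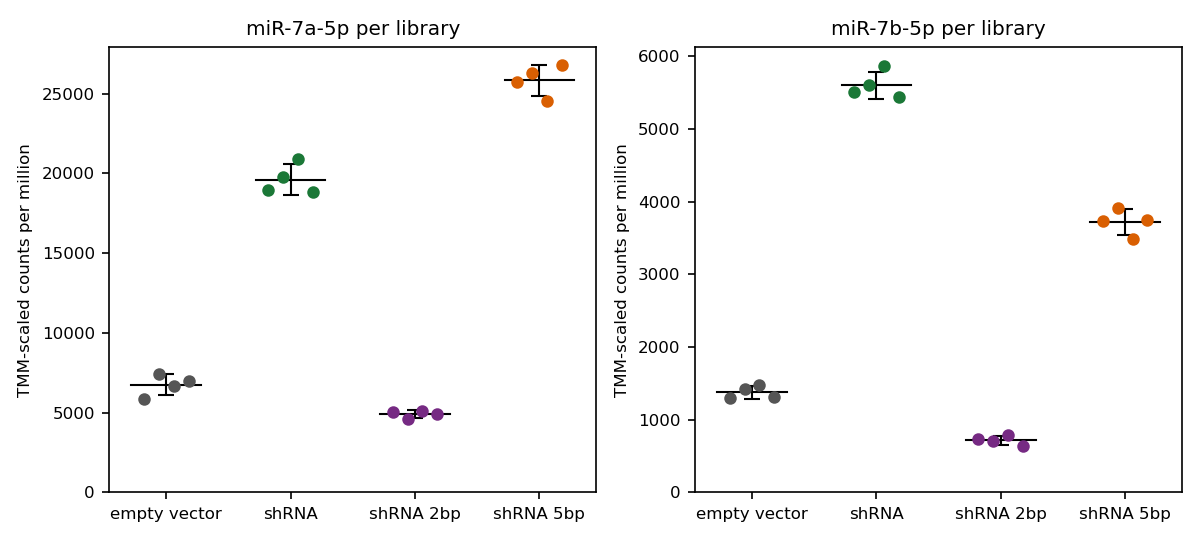
Level (CPM) of miR-7a-5p and miR-7b-5p in each of the 16 libraries, each dot 1 library, with lines for the group mean ± SD. Both were above the empty vector with shRNA (1.54 and 2.02 on the log2 scale) and shRNA_5bp (1.94 and 1.43) and below it with shRNA_2bp (-0.45 and -0.94).

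The hairpin with 2 mutations shifted more miRNAs, and miR-7a-5p and miR-7b-5p moved the other way. MiR-7b-5p fell to 715.9 ± 63.07 CPM (-0.94 ± 0.063, adjusted p = 1.13e-13) and miR-7a-5p to 4917 ± 227.1 CPM (-0.45 ± 0.061, adjusted p = 1.69e-07). Of the opposite arms of miR-7a-5p, miR-7a-1-3p rose (1.17 ± 0.188, from 15.47 to 34.37 CPM, adjusted p = 3.69e-06). The other, miR-7a-2-3p, named after its values were seen, stood at -0.15 (adjusted p = 0.324; -0.35, adjusted p = 0.0286, without shRNA_2bp library 3). MiR-760-3p fell from 1497 ± 93.48 to 193.3 ± 17.46 CPM (-2.95 ± 0.079, adjusted p = 1.08e-22). MiR-3085-3p (-3.16 ± 0.321, adjusted p = 9.68e-10) fell too. MiR-433-3p fell from 3679 ± 248.1 to 770 ± 37.34 CPM (-2.26 ± 0.064, adjusted p = 3.07e-22). MiR-128-3p fell to 240800 ± 11200 CPM (-0.83 ± 0.065, adjusted p = 4.83e-12). The widely stress-induced miR-21a-5p rose from 737.6 to 1790 CPM (1.28 ± 0.07, adjusted p = 1.5e-15), as did miR-376b-3p from 103.9 ± 6.439 to 487.2 ± 35.59 CPM (2.23 ± 0.085, adjusted p = 2.29e-19). MiR-132-3p rose (0.45 ± 0.068) while miR-212-3p from the same transcript fell (-0.72 ± 0.154, adjusted p = 0.000179). Altogether 317 of 483 changed, 161 up and 156 down, 64 and 76 of them more than 2-fold. Complete separation was met by 279 of the 317 and by 286 (59.2%) of all tested miRNAs, against 2.86% by chance. The share of rises was 50.8%, but 61.9% with library-size scaling (median of all miRNAs 0.19 against 0.01) and 38.2% without the filter on low counts (median -0.18).

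In the Dlk1-Dio3 region 48 of 80 miRNAs fell and 7 rose with shRNA_2bp (median -0.81, camera adjusted p = 7.8e-09; adjusted p = 0.0376 with an estimated correlation). Falls included those of miR-770-5p (-2.68 ± 0.111) and miR-370-3p (-1.48 ± 0.053), against the rise of miR-376b-3p. All 9 Microprocessor-independent miRNAs fell (median -1.49, camera adjusted p = 0.00216; adjusted p = 0.188 with an estimated correlation). The largest falls were those of miR-1224-5p (-2.67 ± 0.173, from 94.11 to 14.46 CPM) and miR-877-5p (-2.39 ± 0.209). The miR-30 family rose, 8 of 11 with 0 falls (median 0.63, camera adjusted p = 0.00465; adjusted p = 0.188 with an estimated correlation; miR-30e-3p 1.18 ± 0.058). In the miR-181 family 7 of 8 rose (median 0.78, camera adjusted p = 0.0244; adjusted p = 0.21 with an estimated correlation; miR-181a-5p 1.08 ± 0.066). All 5 members of the miR-34/449 family rose (median 1.67, camera adjusted p = 0.0138; adjusted p = 0.21 with an estimated correlation; miR-34c-3p 2.65 ± 0.295). Of 30 neuron-enriched miRNAs 8 rose and 14 fell (median -0.18, camera adjusted p = 0.353), but 11 and 11 with library-size scaling. Among 19 let-7 members 9 rose and 3 fell (median 0.15, camera adjusted p = 0.278), though 4 rose and 5 fell without the filter on low counts, and 4 rose without shRNA_2bp library 3 or 4. Of 11 miR-17-92 members 5 rose (4 when adjusted over the list alone; 3 without empty-vector library 4 or shRNA_2bp library 1; camera adjusted p = 0.116), with miR-25-3p at 1.09 ± 0.08, and 1 fell without empty-vector library 2, shRNA_2bp library 1 or 4, or shRNA_5bp library 2. Of 4 miR-29 members 3 fell, including miR-29a-3p (-0.41 ± 0.091; -0.22, adjusted p = 0.0531, with library-size scaling).

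As for markers of other cells with shRNA_2bp, of 7 astroglia-leaning miRNAs 4 rose (median 0.51, camera adjusted p = 0.0244; adjusted p = 0.188 with an estimated correlation), including miR-21a-5p and miR-22-5p (1.17 ± 0.085). Of 8 vascular and fibroblast miRNAs 6 rose (7 when adjusted over the list alone), including miR-10a-5p (1.78 ± 0.18) and endothelial miR-126a-3p (0.63 ± 0.063). Their median was 1.35 and the camera adjusted p = 0.0269, but adjusted p = 0.232 with an estimated correlation and 0.055 with library-size scaling. All 4 tested erythroid names rose (2 without empty-vector library 4, shRNA_2bp library 1, 3 or 4, or shRNA_5bp library 2). These are the arms of miR-486a and miR-486b, whose counts were identical for the same arm, so they are not 4 separate markers. Of 3 oligodendrocyte miRNAs 2 rose (1 without empty-vector library 2 or 4, shRNA_2bp library 2, 3 or 4, or shRNA_5bp library 2). Of the 2 tested microglia miRNAs, both also on the inflammation list, 1 rose. Of 4 inflammation miRNAs 3 rose, with miR-146a-5p at 0.82 ± 0.13.

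**Figure D3:**
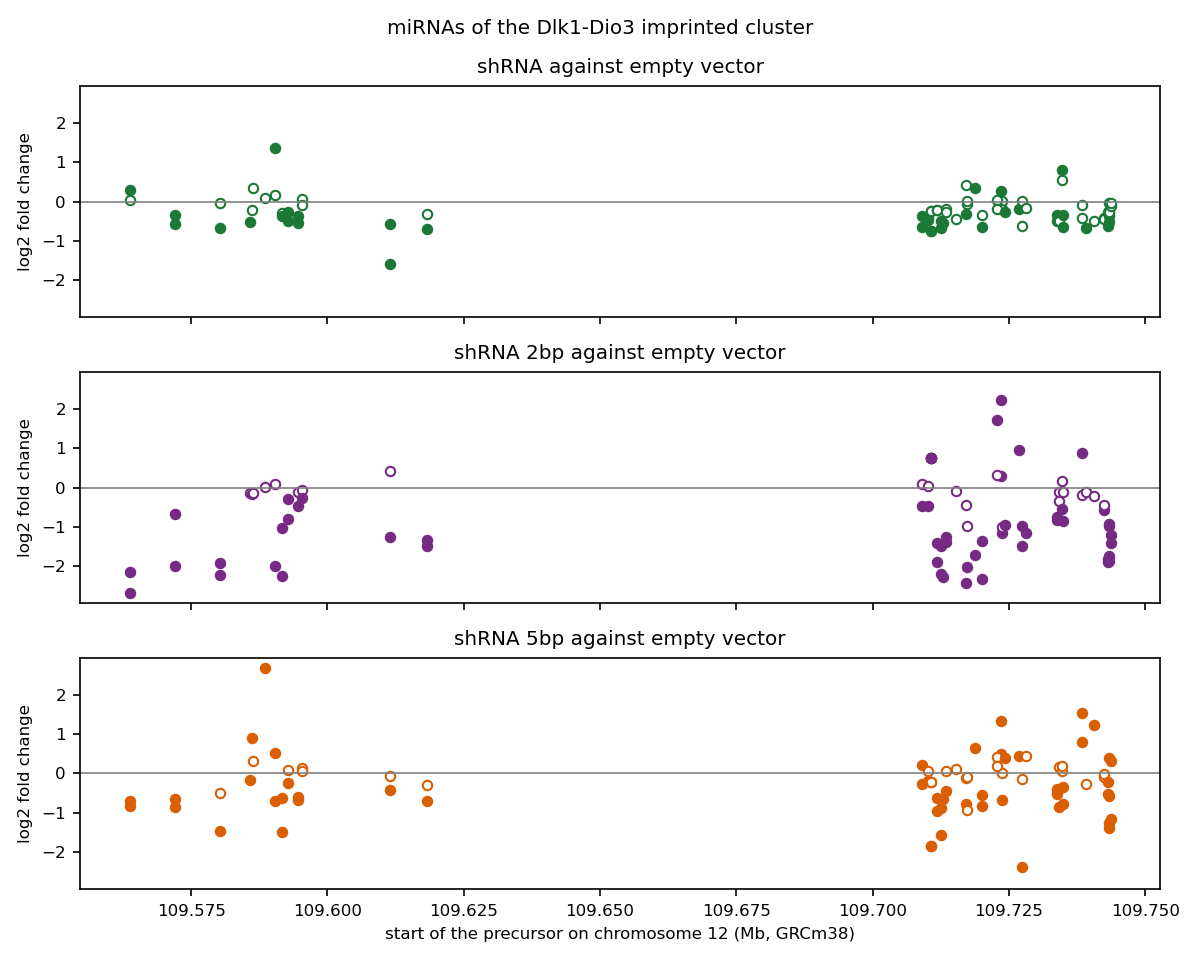
Log2 fold changes against the empty vector of the 80 tested miRNAs of the Dlk1-Dio3 region, placed by their position on chromosome 12 (109563692 to 109743795), in 1 panel per hairpin with filled dots for an adjusted p below 0.05. More members fell than rose with shRNA (36 and 5), shRNA_2bp (48 and 7) and shRNA_5bp (40 and 14; 26 and 23 with library-size scaling).

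With 5 mutations miR-7a-5p and miR-7b-5p were again raised, miR-7a-5p to 25840 ± 982.6 CPM (1.94 ± 0.062, adjusted p = 1.8e-20) and miR-7b-5p to 3719 ± 176.3 CPM (1.43 ± 0.062, adjusted p = 1.59e-17). MiR-129-2-3p (1.56 ± 0.113), miR-212-3p (1.32 ± 0.131), miR-23a-3p (1.31 ± 0.141) and miR-132-3p (1.07 ± 0.068, adjusted p = 1.05e-13) rose. The largest rises were of names with little known function that were scarce with the empty vector. MiR-696 rose by 5.75 ± 0.361 (from 1.593 to 105.1 CPM), miR-1195 by 4.69 ± 0.267 (from 5.117 to 150.1 CPM), and miR-690 went from 37.91 to 887.1 CPM. The precursor of miR-1195 shares 20 bases with another non-coding RNA. So did 9 of the 25 with a sequence among the 29 miRNAs more than 4-fold higher, against 9 of 450 others. Fisher's exact p was 2.38e-08, with related names taken as independent. The 29 held 0.0281 ± 0.00577% of counts with the empty vector and 0.433 ± 0.123% with shRNA_5bp. MiR-433-3p fell to 1309 CPM (-1.49 ± 0.062, adjusted p = 1.03e-17), as did miR-760-3p (-1.43 ± 0.073), miR-375-3p (-1.66 ± 0.208), miR-184-3p (-1.64 ± 0.267) and miR-128-3p (-0.81 ± 0.065). Altogether 281 of 483 changed, 152 up and 129 down, 61 and 34 of them more than 2-fold. Groups were completely separated for 232 of the 281 and for 243 (50.3%) of all tested miRNAs, against 2.86% by chance. The share of rises was 54.1%, but 72.7% with library-size scaling (median of all miRNAs 0.3 against 0.06) and 38.2% without the filter on low counts (median -0.28).

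In the Dlk1-Dio3 region 40 miRNAs fell and 14 rose with shRNA_5bp (median -0.25, camera adjusted p = 0.00216; adjusted p = 0.21 with an estimated correlation), but 26 fell and 23 rose with library-size scaling (median -0.01). MiR-323-5p (-1.58 ± 0.169), miR-493-5p (-1.48 ± 0.145) and miR-370-3p (-0.71 ± 0.052) fell, and miR-376b-3p (1.33 ± 0.086) rose. Members of the let-7 and miR-98 list restrain growth and rise as neurons mature. Of these 9 of 19 fell and 2 rose (median -0.35, camera adjusted p = 0.0302), but 6 fell and 5 rose with library-size scaling (adjusted p = 0.095). The list had adjusted p = 0.247 with an estimated correlation. Let-7a-5p (-0.59 ± 0.069) and let-7d-5p (-0.61 ± 0.057) fell, let-7j rose (0.73 ± 0.061), and without empty-vector library 2 only 1 member rose. Of 9 Microprocessor-independent miRNAs 6 fell (median -0.61, camera adjusted p = 0.0476; adjusted p = 0.284 with an estimated correlation), but 5 fell and 2 rose with library-size scaling (adjusted p = 0.0559). That list's p was 0.0526 without empty-vector library 3, 0.0548 without shRNA_2bp library 1, 0.0679 without shRNA_5bp library 3 and 0.0655 without shRNA_5bp library 4. MiR-877-3p fell by 1.31 (SE 0.204). Of 30 neuron-enriched miRNAs 14 rose and 7 fell (15 and 7 when adjusted over the list alone; median 0.18, camera adjusted p = 0.198), but 11 rose and 12 fell without the filter on low counts. In the miR-30 family 7 of 11 rose and 2 fell (median 0.28, adjusted p = 0.229; miR-30a-5p 0.66 ± 0.059), and 1 fell without empty-vector library 1 or 2, shRNA library 4, shRNA_2bp library 1, or shRNA_5bp library 1 or 3. In the miR-181 family 5 of 8 rose (median 0.35, adjusted p = 0.115; miR-181a-5p 0.97 ± 0.066). Only 1 of 5 miR-34/449 miRNAs rose, with a median of 0.29 (adjusted p = 0.83) that was -0.07 without the filter on low counts, and 2 rose without shRNA_5bp library 1. None rose without empty-vector library 2 or 3 or shRNA_5bp library 3 or 4, and 1 fell without empty-vector library 3 or shRNA_5bp library 2. Of 11 miR-17-92 members 3 rose (1 without empty-vector library 2; median 0.22, but -0.06 without the filter on low counts; adjusted p = 0.339), and 0 of 4 miR-29 members changed, though 2 rose with library-size scaling.

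Among markers of other cells 4 of 7 astroglia-leaning miRNAs rose with shRNA_5bp (median 0.4, camera adjusted p = 0.116; 2 without empty-vector library 3). MiR-22-5p stood at 0.40 ± 0.088 (0.17, adjusted p = 0.32, without the filter on low counts). Of 8 vascular and fibroblast miRNAs 6 rose (7 when adjusted over the list alone), with miR-10b-5p at 1.22 ± 0.305 and miR-126a-3p at 0.58 ± 0.063. The camera adjusted p was 0.081, and 0.0338 without shRNA_5bp library 1. Of 4 inflammation miRNAs 3 rose, with miR-146b-5p at 0.45 ± 0.058. Of the 2 tested microglia miRNAs, both also on that list, 1 rose (0 without empty-vector library 2 or shRNA_5bp library 4). Of 3 oligodendrocyte and 4 erythroid miRNAs 0 changed, although all 4 erythroid names, the arms of miR-486a and miR-486b, rose with library-size scaling.

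**Figure D4:**
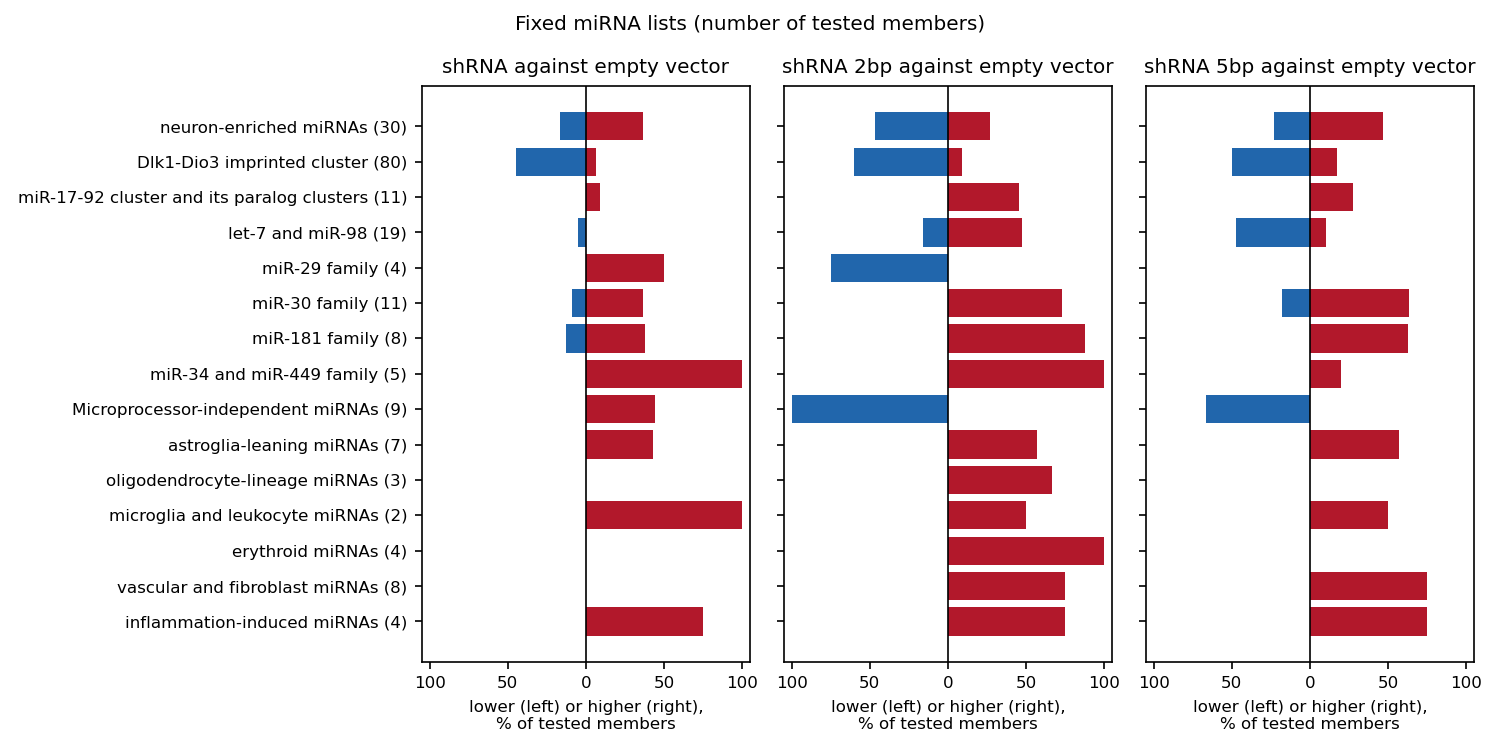
Percentage of the tested members of each fixed list (number in brackets) that fell (left, blue) or rose (right, red) against the empty vector, in 1 panel per hairpin. Of 80 Dlk1-Dio3 miRNAs 36, 48 and 40 fell with shRNA, shRNA_2bp and shRNA_5bp (26 in the last with library-size scaling, against 23 rises), and of 9 Microprocessor-independent miRNAs 0, 9 and 6 fell.

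Across the 3 hairpins averaged, miR-433-3p fell most clearly (-1.37 ± 0.046, adjusted p = 7.19e-20), with all 12 hairpin libraries below all 4 empty-vector libraries. MiR-323-5p (-1.48 ± 0.117), miR-493-5p (-1.36 ± 0.102), miR-1a-3p (-1.19 ± 0.125) and miR-128-3p (-0.67 ± 0.051, adjusted p = 4.5e-12) fell likewise. MiR-376b-3p (1.28 ± 0.072, adjusted p = 6.71e-15), miR-129-2-3p (1.23 ± 0.096), miR-181a-5p (0.93 ± 0.056) and miR-132-3p (0.83 ± 0.058) rose. In all, 289 changed, 152 up and 137 down, and 60 (12.4%) of all tested miRNAs were completely separated, against 0.11% by chance. Their share of rises (52.6%) was 69.4% with library-size scaling (median of all miRNAs 0.23 against 0.04) and 35.4% without the filter on low counts (median -0.2). MiR-7a-5p (1.01 ± 0.052) and miR-7b-5p (0.84 ± 0.052) rose in this average too, though they fell with shRNA_2bp and so were not separated.

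For the mean of the hairpins, 50 of 80 Dlk1-Dio3 miRNAs fell and 6 rose (median -0.44, camera adjusted p = 3.31e-10; adjusted p = 0.0304 with an estimated correlation). When adjusted over the list alone it was 51 and 6, and 3 rose without empty-vector library 2 or 4. Of 9 Microprocessor-independent miRNAs 7 fell (median -0.76, adjusted p = 0.0185; adjusted p = 0.232 with an estimated correlation), with miR-1224-5p at -0.98 ± 0.109. In the miR-30 family 7 of 11 rose (median 0.43, adjusted p = 0.0269; adjusted p = 0.21 with an estimated correlation), and 1 fell without empty-vector library 4, shRNA_2bp library 3 or 4, or shRNA_5bp library 2. In the miR-181 family 6 of 8 rose (median 0.25, adjusted p = 0.0455; adjusted p = 0.232 with an estimated correlation). The miR-181 call was lost without empty-vector library 3 (0.0533) or 4 (0.0786) or shRNA_5bp library 2 (0.0598). Only 3 members rose without empty-vector library 4, shRNA_2bp library 3 or 4, or shRNA_5bp library 2. Of the miR-34/449 family 4 of 5 rose (5 when adjusted over the list alone; median 0.94, adjusted p = 0.0333; adjusted p = 0.247 with an estimated correlation; 0.07 with library-size scaling). That call was lost without empty-vector library 1 (0.0562) or 3 (0.0565) or shRNA library 4 (0.0501). Astroglia-leaning miRNAs rose (5 of 7, median 0.54, adjusted p = 0.0269; adjusted p = 0.188 with an estimated correlation). So did vascular and fibroblast miRNAs (8 of 8, median 0.94, adjusted p = 0.0368; adjusted p = 0.247 with an estimated correlation; 0.0891 with library-size scaling), though 5 rose without empty-vector library 4 or shRNA_2bp library 3. Of the neuron-enriched miRNAs 15 rose and 9 fell (adjusted p = 0.369). Of let-7 and miR-98 members 2 rose and 4 fell (adjusted p = 0.536; 7 fell without shRNA_2bp library 4), but 9 rose and 2 fell with library-size scaling. Of 11 miR-17-92 members 4 rose (adjusted p = 0.207; 2 without empty-vector library 4, shRNA_2bp library 4 or shRNA_5bp library 2). Of miR-29 members 1 fell (0 when adjusted over the list alone, and 0 without empty-vector library 1 or 2, shRNA library 1 or 3, shRNA_2bp library 1 or shRNA_5bp library 4). All 4 inflammation miRNAs rose, among them both tested microglia miRNAs. Only 1 microglia miRNA rose without empty-vector library 2 or 4, shRNA library 3, shRNA_2bp library 1, or shRNA_5bp library 1 or 3. In those fits miR-155-5p was not called (adjusted p = 0.0545 to 0.2). Its mean of 0.69 came from shRNA (2.19), against -0.01 with shRNA_2bp and -0.11 with shRNA_5bp. There were 0 changes among oligodendrocyte and erythroid miRNAs, against 2 and 4 rises with library-size scaling, the 4 being the arms of miR-486a and miR-486b. Without empty-vector library 3, shRNA library 1 or 4, shRNA_2bp library 2 or shRNA_5bp library 3, 1 oligodendrocyte miRNA rose.

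Compared with the unmutated hairpin, shRNA_2bp had lower miR-7b-5p (-2.97 ± 0.066, adjusted p = 7.88e-25) and miR-7a-5p (-2 ± 0.063, adjusted p = 3.09e-21). MiR-760-3p (-3.14 ± 0.079, adjusted p = 1.07e-23), miR-770-5p (-2.99 ± 0.111) and the mirtron miR-1224-5p (-2.88 ± 0.171) fell, and miR-466i-5p (2.45) and miR-3473b (2.50), whose precursors share 20 bases with other non-coding RNAs, rose. In total 312 changed, 150 up and 162 down, and all 9 Microprocessor-independent miRNAs fell (median -1.49). With shRNA_5bp against shRNA, miR-7b-5p fell by 0.59 (SE 0.061, adjusted p = 2.6e-09) while miR-7a-5p rose by 0.40 ± 0.06 (adjusted p = 2.24e-06). The latter was 0.23 without shRNA library 1 or shRNA_5bp library 4, 0.24 without shRNA library 2, and 0.25 without empty-vector library 2 or 3. MiR-696 (5.87) and miR-1195 (4.59) rose and miR-760-3p fell (-1.63 ± 0.073), among 137 rises and 119 falls. That split depended on the libraries, as without shRNA library 3 it was 90 rises among 250 changes. Without empty-vector library 2 or 3, shRNA library 1, 2 or 3 or shRNA_5bp library 4 rises made up 36 to 38.2%, and without the filter on low counts rises made up 33.7% against 53.5% (median of all miRNAs -0.28 against 0). With shRNA_5bp against shRNA_2bp, miR-7a-5p (2.39 ± 0.064, adjusted p = 9.91e-23), miR-7b-5p (2.38 ± 0.065, adjusted p = 1.11e-22), miR-1224-5p (2.18) and miR-212-3p (2.04) rose, while miR-34b-3p (-1.61) and miR-10a-5p (-1.58) fell. There were 178 rises and 110 falls, 61.8% rises against 51.7% without shRNA library 2 and 49.6% when only those 2 groups were fitted. In the Dlk1-Dio3 region 43 members rose and 10 fell, and 13 of 19 let-7 and miR-98 members and all 5 of miR-34/449 fell (median -1.58).

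Of the miRNAs changed by any hairpin (405), 67 moved in the same direction with all 3, 30 up and 37 down, against 10 and 6.3 if calls in the 3 comparisons were independent. Among the 67 miR-672-5p (0.92, 0.88 and 0.94 with shRNA, shRNA_2bp and shRNA_5bp), miR-129-2-3p (1.20, 0.94 and 1.56) and miR-181a-5p (0.75, 1.08 and 0.97) rose. MiR-370-3p (-0.70, -1.48 and -0.71), miR-433-3p (-0.36, -2.26 and -1.49) and miR-128-3p (-0.37, -0.83 and -0.81) fell. A further 36 changed with all 3 but not in 1 direction, miR-7a-5p and miR-7b-5p among them. The shared control enters every one of these comparisons, so the comparisons were repeated with different control libraries for the 2 hairpins of a pair. Between shRNA_2bp and shRNA_5bp, 175 miRNAs moved the same way and 35 opposite ways, and 150 and 27 with split controls (r = 0.58, and 0.6 with split controls, against 0.32 in 50 simulations with the shared control and no hairpin effect). Between shRNA and shRNA_5bp the numbers were 103 and 22, and 74 and 12 with split controls (r = 0.32, 0.36 with split controls, and 0.40 in these simulations). Between shRNA and shRNA_2bp they were 82 and 47, and 56 and 31 with split controls (r = 0.24, 0.22 with split controls, and 0.42 in simulations). The covariance of the fold changes, to which the shared control adds a fixed amount, was 0.721, 0.173 and 0.121 in that order, against 0.017 in the simulations.

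The 2 arms of each miRNA precursor were compared within each library over 119 precursors with both arms tested, as the median log2 ratio of the rarer to the commoner arm. That median was -3.477 ± 0.09 with the empty vector, -3.399 ± 0.12 with shRNA, -3.357 ± 0.07 with shRNA_2bp and -3.363 ± 0.171 with shRNA_5bp (mean ± SD over 4 libraries). The differences of 0.079, 0.12 and 0.114 were not called (exact p = 0.4286, 0.0857 and 0.3143; adjusted p = 0.4286, 0.2571 and 0.4286). The first was -0.008 with thinned libraries, and 0.029 to 0.051 without empty-vector library 2 or 4, shRNA library 3 or 4, shRNA_2bp library 3 or 4, or any shRNA_5bp library. The second was 0.058 with thinned libraries. The third was 0.19 with thinned libraries or without shRNA_5bp library 1, 0.046 without shRNA_5bp library 2 and 0.075 without shRNA_5bp library 4. With 4 libraries against 4 the smallest possible exact p is 0.0286. After adjustment over the hairpins, a shift in a lone hairpin could not pass the threshold whatever its size. These tests thus cannot tell an unchanged arm balance from a shift with a single hairpin.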

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

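All tests weighed in this part, on depth, GC content, other RNAs, precursor level and read sharing, were chosen after seeing the results they bear on.

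Of 228 groups of 4 libraries checked, 11 held a library far from the other 3, where chance would give about 1 in 20, or 11.4. For miR-155-5p, replicate 1 of shRNA_2bp stood at 5.99 CPM against 2.13 to 2.46 in the others. For miR-466i-5p replicate 2 of shRNA_2bp at 68.8 CPM against 36.8 to 40.1, and for let-7d-5p replicate 1 of shRNA_2bp at 6410 CPM against 5810 to 5840. In the empty vector, replicate 1 stood at 61.1 CPM for miR-23a-3p (others 39.4 to 43.1), at 39 CPM for miR-877-5p (29.9 to 31.1), at 22.1 CPM for miR-7a-1-3p (12.7 to 13.9) and at 92.7 CPM for miR-22-5p (96 to 96.6), and replicate 2 at 449000 CPM for miR-128-3p (418000 to 421000). With shRNA_5bp, replicate 3 stood at 1010 CPM for miR-21a-5p (862 to 886) and replicate 1 at 156 CPM for miR-431-5p (174 to 177), and with shRNA replicate 4 stood at 306 CPM for miR-770-5p (343 to 348). No cause was tested.

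Some named miRNAs changed in opposite directions with 2 hairpins, and the direct comparison of those hairpins also had an adjusted p below 0.05. Between shRNA_2bp and shRNA these were miR-7b-5p (-2.97), miR-7a-5p (-2), miR-760-3p (-3.14), miR-770-5p (-2.99), miR-877-5p (-2.81), miR-212-3p (-1.64), miR-668-3p (-1.34), miR-1839-5p (-1.09), miR-29a-3p (-1) and miR-30e-3p (1.34). For shRNA_5bp against shRNA the same held for miR-760-3p (-1.63), miR-877-5p (-1.3), miR-770-5p (-1.15) and miR-30e-3p (0.41). The last was 0.26 without empty-vector replicate 2 or 3 or shRNA replicate 2, and 0.24 without shRNA replicate 3. For shRNA_5bp against shRNA_2bp it held for miR-7a-5p (2.39), miR-7b-5p (2.38) and miR-212-3p (2.04). The changes of miR-760-3p (0.19), miR-770-5p (0.31), miR-877-5p (0.42) and miR-30e-3p (-0.15) with shRNA against the empty vector were small. The call was lost for miR-770-5p and miR-877-5p without empty-vector replicate 4 (adjusted p = 0.0697 and 0.109). It was lost for miR-760-3p without empty-vector replicate 1 or 4, shRNA_2bp replicate 3 or 4 or shRNA_5bp replicate 2 (0.0694 to 0.232), and for miR-30e-3p without empty-vector replicate 1, 2 or 3, any shRNA replicate, shRNA_2bp replicate 1 or 2 or shRNA_5bp replicate 4 (0.0511 to 0.415).

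The first pattern weighed was the larger number of miRNAs changed with shRNA_2bp and shRNA_5bp than with shRNA (ratios 1.89 and 1.67), in groups that were also sequenced less deeply. With every library thinned to the smallest total the ratios were 2.25 (1.93 to 2.53 over 20 draws) and 2.07 (1.82 to 2.31), which excludes depth as the whole cause. After GC correction they were 1.95 and 1.8 (1.69 and 1.62 with the replicate block), which excludes the GC proxy as the whole cause. For shRNA_2bp the surplus of changed miRNAs over shRNA was 131 without the 18 miRNAs matching an annotated other RNA, and 149 with them. For shRNA_5bp it was 104 without and 113 with them. Without them and with each library left out, the surpluses were 112 to 150 and 73 to 125. Only 18 miRNAs were removed, so surpluses this large could hardly have vanished, and the test cannot decide whether those matches contributed. The surplus replaced the ratio as the measure after the result was seen. Without the 18 the ratios were 1.82 and 1.65 (1.65 to 2.14 and 1.41 to 1.95 with each library left out). Leaving out also the miRNAs more than 4-fold higher with shRNA_5bp gave ratios of 1.72 and 1.47. Those miRNAs were picked from the shRNA_5bp calls, so these ratios decide nothing. Fragments without an annotated match were not tested otherwise. A batch that ran along with the groups could not be tested because the labels give none, and that the mutated hairpins disturb more miRNAs remains a hypothesis.

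The second pattern was the group of 29 miRNAs more than 4-fold higher with shRNA_5bp, such as miR-696 and miR-690. Among the 25 with a precursor sequence 9 (36%) matched another RNA, against 9 of 450 others (2%). The odds ratio was 26.9 (interval 8.3 to 89, Fisher's exact p = 2.38e-08), as fragments of other RNAs counted as miRNAs would give. Fisher's test takes names as independent, but related ones such as miR-3470a and miR-3470b moved alike (3.88 and 3.79 with shRNA_5bp). The p and interval may therefore be too narrow. Names without an arm suffix were 22 of the 29 against 25 of 454 others, and the 29 held 0.0281 ± 0.00577% of counts with the empty vector, 0.0337 ± 0.00335% with shRNA, 0.104 ± 0.00604% with shRNA_2bp and 0.433 ± 0.123% with shRNA_5bp (± SD). Depth was excluded as the whole cause, since each shRNA_5bp library, when left out of the choice, had a log2 share 1.18 to 2.25 above the highest of shRNA_2bp, the deepest (2496036 counts) holding 0.275% against 0.109 to 0.121% in the shallower shRNA_2bp libraries. Within shRNA_5bp the share of the 29 was 0.508, 0.553, 0.394 and 0.278% from the smallest to the largest library, so depth may add to it, and no biological explanation was tested.

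The third pattern was the rise of miR-7a-5p and miR-7b-5p with shRNA and shRNA_5bp and their fall with shRNA_2bp, where the opposite arms stood at 1.17 (miR-7a-1-3p, adjusted p = 3.69e-06) and -0.15 (miR-7a-2-3p, adjusted p = 0.324). The highest upper bound of the opposite arms was 0.64 with shRNA and 1.22 with shRNA_5bp, below the lower bounds of miR-7a-5p (1.41 and 1.8). The opposite arms thus rose less than miR-7a-5p. This bears on the level of miR-7a precursor only if the scarce opposite arms follow it. With shRNA_2bp miR-7a-1-3p rose by 1.17 while miR-7a-5p stood at -0.45, so more precursor cannot be excluded. Without empty-vector library 1, miR-7a-1-3p with shRNA was 0.46 (edgeR adjusted p = 0.0331). For shRNA, a fixed share of miR-7a-5p reads counted as miR-7b-5p was excluded as the whole cause of the miR-7b-5p rise, but not as a part. There the log2 ratio of miR-7b-5p to miR-7a-5p was 0.48 higher than with the empty vector (exact p = 0.0286). For shRNA_5bp, where this ratio was 0.51 lower (-0.51, exact p = 0.0286), the explanations cannot be told apart. Reads derived from the hairpin itself were not tested, because the labels do not give its sequence. Less precursor with shRNA_2bp and a biological explanation were not tested.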

How the results depend on the processing

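Alternatives with thinned libraries, GC correction, both libraries under 1 M counts left out, the top miRNA left out and other-RNA matches left out were chosen after seeing the data; the others were planned. Counts of changed miRNAs, with 1 draw of thinned libraries, stayed within 1.5 times: 118 to 194 for shRNA, 241 to 333 for shRNA_2bp, 215 to 309 for shRNA_5bp, 217 to 310 for their mean, 237 to 332 and 195 to 279 for shRNA_2bp and shRNA_5bp against shRNA, 234 to 298 for shRNA_5bp against shRNA_2bp, and 49 to 79 for the miRNAs shared by all hairpins. Over 20 thinned draws shRNA gave 96 to 122, lower by more than 1.5 times in 13 draws, where fewer counts were left, shRNA_2bp 226 to 247 and shRNA_5bp 210 to 227. Leaving out 1 library gave 145 to 176, 290 to 318, 261 to 282, 255 to 295, 290 to 312, 233 to 260, 262 to 289 and 54 to 76 in that order, 17 to 20 list calls, and arm ratio differences of 0.029 to 0.103, 0.099 to 0.156 and 0.046 to 0.19. Over the other settings the arm ratio differences for shRNA ran from -0.008 (thinned libraries) to 0.119 (prior count 0.5). The difference for shRNA was 0.036 at a mean CPM of 10 or more in both arms. For shRNA_2bp they ran from 0.058 (thinned) to 0.131, and for shRNA_5bp from 0.114 to 0.19 (thinned). None was called, but the exact test could not call a shift in a lone hairpin. List calls fell from 19 to 12 with thinned libraries, where fewer counts were left. They fell to 3 with an estimated correlation, which was 0.03 to 0.31 depending on the list and above the preset 0.01 in every list. Most list calls thus rest on a preset correlation lower than the one estimated. Summing precursor entries of the same miRNA gave no value because no name occurred more than once.

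With the replicate block the counts were 185, 324, 294, 300, 319, 266 and 298, the overlap 76 and list calls 18, the Microprocessor-independent list with shRNA_5bp passing no longer (adjusted p = 0.0707). For shRNA_5bp the lowest correlations of libraries sharing a number were -0.06 with the empty vector, -0.039 with shRNA and -0.021 with shRNA_2bp, and 2, 4 and 6 of 8 libraries correlated best with their own number, a hint from the data only. For the arm ratio the blocked exact sign-flip test gave adjusted p values of 0.75, 0.375 and 0.5625. With 4 pairs that test could not pass the threshold whatever the values, so it decides nothing. With shRNA_2bp every library lay above the empty-vector library of its number, which did not hold for shRNA or shRNA_5bp. Of 316 results of miRNAs chosen by the naming rule, 309 kept direction and call with the block. Calls were gained for let-7g-5p (0.11) and let-7i-5p (-0.12) with shRNA, let-7i-5p with shRNA_2bp (-0.1), let-7c-5p (-0.14) and let-7f-5p (-0.11) with shRNA_5bp and miR-125b-5p for the mean (0.12), and 1 was lost, miR-29c-5p with shRNA_2bp (-0.47).

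Of 9600 values of named miRNAs, 9094 kept direction and call, 349 were weaker, 137 stronger and 20 reversed, and the cause was not tested except where stated. Thinned libraries reversed miR-299a-3p (0.18, and 0.18 with the block) and miR-299b-3p (0.16 and 0.16) with shRNA. Library-size scaling, which moves all medians up, reversed miR-9-5p with shRNA (0.14), let-7c-5p with shRNA_2bp (0.17), let-7f-5p with shRNA_5bp (0.13), and let-7c-5p (0.15) and let-7i-5p (0.12) for the mean. Without the filter on low counts, which moved the median down, the reversed values with shRNA_5bp were let-7g-5p (0), let-7i-5p (-0.22), miR-125b-5p (-0.2), miR-26a-5p (-0.18), miR-29a-3p (-0.22), miR-9-5p (-0.03) and miR-99a-5p (-0.08). GC correction reversed miR-29a-3p with shRNA_5bp (-0.26, and -0.26 with the block) and let-7f-5p for the mean (-0.11 and -0.11). Depth limits rare miRNAs most: 3 counts stood for 0.269 to 3.61 CPM depending on the library.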

Other observations

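The correlation of the 2 arms of a precursor was planned before its result was seen, while the genomic clusters and the splits of the libraries were tests chosen after seeing the results.

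Within the Dlk1-Dio3 region on chromosome 12, the 20 tested miRNAs from Mir770 to Mir136, in and beyond the Meg3 gene, included 9 falls and 2 rises with shRNA, 13 and 0 with shRNA_2bp, and 12 and 3 with shRNA_5bp. The 5 miRNAs of the Rian part, ending with miR-370-3p, included 4, 4 and 3 falls with 0 rises. The 57 miRNAs from Mir379 to Mir410 included 24 falls and 3 rises, 33 and 7, and 26 and 11. After GC correction 49 of the 80 miRNAs of the fixed Dlk1-Dio3 list, which holds 2 fewer than these 3 parts, fell and 8 rose with shRNA_2bp (median -0.82), and 41 fell and 13 rose with shRNA_5bp (median -0.29). Elsewhere, the 7 miRNAs of the Clcn5 cluster on the X chromosome (7237683 to 7248497), hosted in introns of a chloride transporter gene, included 3 rises and 0 falls with shRNA (median 0.36), 1 and 3 with shRNA_2bp (median -0.31), and 5 and 1 with shRNA_5bp (median 0.82). The Mcm7 cluster of miR-25 and miR-106b included 1, 3 and 1 rises among 5, with 0 falls. The Spaca6 cluster of miR-99b, let-7e and miR-125a included 2, 3 and 3 falls among 6, with 0, 1 and 1 rises.

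The hypothesis that changes of precursor level contributed to the changes of mature miRNAs predicted that the 2 arms of a precursor would move together. Over 119 precursors the arms' log2 fold changes correlated with r = 0.52 with shRNA, 0.71 with shRNA_2bp and 0.42 with shRNA_5bp (permutation p = 1e-05 each, the smallest that 100000 resamples can give), with 83, 88 and 83 precursors showing the same sign. Precursors of 1 cluster are not independent, the arms share libraries and scaling, and the result leaves room for other causes.

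Splits of the same libraries into other groups of equal size were used to ask whether chance can be excluded as the source of the counts of changed miRNAs. The real grouping gave 168 changes with shRNA, 317 with shRNA_2bp and 281 with shRNA_5bp, against at most 1, 1 and 0 in the other splits of 35. It gave 312, 256 and 288 between hairpins against at most 0, and 289 for the mean of the hairpins against at most 30 in 100 splits. In each case 1 split, the real one, gave as many, a share of 1 in 35 or 1 in 100. That speaks only against a random sorting of independent libraries. The labels do not give separate cultures or animals, so chance differences between cultures are not excluded. The other splits mixed the real groups, which widens the spread within them. They also ignored replicate numbers, which passed the pairing check for shRNA with the empty vector and shRNA_2bp with shRNA, so 1 in 35 need not hold there.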
